A study of Mus musculus with 100 samples.

How the data were processed

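Messenger RNA was sequenced from mouse V6.5 embryonic stem cells, a hybrid ES cell line, after each subunit of TFIID or Mediator had been lowered by a short hairpin RNA (shRNA). Hairpins against Gcn5 (gene Kat2a) and Usp22, subunits of the SAGA coactivator, were included. Per the labels, cells were depleted of feeder fibroblasts, transfected with 1.8 µg of shRNA plasmid, given puromycin from 24 h and selected for 72 h, and libraries were made with a KAPA stranded mRNA kit. There are 100 libraries in 50 groups of 2: 47 knockdowns and 3 groups with a control plasmid. Each control label lists the knockdowns it is for, read here as control set A (15 TFIID knockdowns with Med15, Med16, Med23, Med24 and Med25), set B (Gcn5, Usp22 and 23 Mediator knockdowns) and set C (Med1 and Med14). All groups come from these labels. The labels do not say that the 2 libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries.

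Per the labels, the authors aligned reads with TopHat2 to the mm9 build. The deposited tables hold RPKM (reads scaled by transcript length and by library size), 1 value per RefSeq transcript. The version of the aligner, the counting tool, its strand setting and its filters are not given in the sources used here. The tables list transcripts without positions. Of the 34995 lines in each table, 33565 were named from a RefSeq table of mouse genome release GRCm38.p6 and 189 more from GENCODE vM21, while 1241 stayed unnamed. Repeated identifiers (140 lines) were counted once. Each of the 24206 named genes took the value of its transcript with the highest mean RPKM over the 100 libraries (5140 genes had several transcripts). RPKM values are shares of a library. Without a spike-in they cannot show a shift common to all genes, and the fold changes below are relative to the average gene.

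Raw counts were not used here. Low RPKM values are whole multiples of one step per library, and 99.9% of values above 0 were whole read numbers within 0.01 reads once that step was known. The step gave each library's RPKM denominator, 17.25 to 39.32 M reads (median 23.32 M), and 1 read on a kilobase of transcript equals 0.025 to 0.058 RPKM. The depth estimate was tested on simulated data.

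Tests were made with limma 3.58.1 in R 4.3.3. Values were log2(RPKM + 1), and 12974 genes with at least 1 RPKM in at least 2 libraries were tested. The pseudocount of 1 makes the fold change of a gene near or under 1 RPKM smaller than the ratio of its levels. All 100 libraries entered 1 limma-trend fit with 1 coefficient per group, 50 residual degrees of freedom (54.5 with the prior) and no covariate. Each knockdown was compared with the control group its label names. The label of control_B covers all Mediator subunits except 5 and so can be read to include Med1 and Med14, which the label of control_C names; these 2 were compared with control_C, and with control_B as another setting. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, two-sided, and the 47 targets were adjusted among themselves. Errors beside log2 fold changes are standard errors from this fit, and errors beside RPKM values are standard deviations over the 2 libraries. The change in the shTaf12 libraries was compared with the change in the shMed4 libraries by a contrast of contrasts, and their shared calls by Fisher's exact test. TFIID was compared with the Mediator tail (15 against 5 knockdowns), and the kinase module with the head and middle modules (4 against 15), by limma-trend on the mean of the 2 libraries of each knockdown, so that the knockdown, by its label, is the unit. Subunits were assigned to modules from general knowledge of Mediator before the data were examined. Each of these comparisons was set beside 100 splits of the same knockdowns into groups of the same sizes, the real split included.

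There were 34 gene lists: general, naive and primed pluripotency, mesendoderm, primitive endoderm, trophectoderm, neuroectoderm, two-cell-like, germline, p53 targets, integrated stress response, interferon response, cholesterol synthesis, hypoxia and glycolysis, heat shock, immediate early genes, targets of ERK, Wnt, TGF-beta and BMP, LIF-Stat3 and retinoic acid, Hox, imprinted genes, ribosome biogenesis, G1/S, G2/M, ribosomal proteins, subunits of TFIID, TFIID paralogs, subunits of Mediator, SAGA and Pol II, general transcription factors, and markers of fibroblast feeders. Of 493 entries, 492 matched a named gene. The lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move one way on balance without comparing them with other genes. Test results were adjusted over the lists within each contrast, and members were also adjusted over the list alone. Recurrent genes were those called in one direction in at least 8 of 15 TFIID or 12 of 23 set B Mediator knockdowns, beside 20 simulations of unchanged groups that share the same controls. Apart from the comparison with splits and the tests named below as later, the groups, tests, lists and thresholds were chosen before the data were examined. So was the first group of other settings below.

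Genes named in the text follow a rule also fixed before the data were examined: the target, the 8 highest and 8 lowest log2 fold changes among called genes of at least 2 RPKM on average whose knockdown libraries lie on one side of both controls (predicted and unnamed transcripts, microRNAs and small RNAs left out), up to 4 members of each list with the smallest p, the 8 genes called in most knockdowns in each direction, and 3 highest and 3 lowest genes for the 3 other knockdowns with the most calls. Genes outside it are said to be so, and not every gene it selects is printed.

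The other settings changed 1 choice at a time: a pseudocount of 0.1, no filter on low values, upper-quartile scaling, a fold change threshold, other sets of libraries in the fit, the other knockdowns as the reference, the replicate number as a block, and leaving out each library of the shTaf12 and shMed4 comparisons, and each control library, in turn. Added after target levels had been seen were a fit with 1 library per knockdown in sets A and C (78 libraries, 28 residual degrees of freedom), a gene level from the mean over transcripts, limma-voom on the whole read numbers (possible for 12972 of the 12974 genes) and upper-quartile scaling of the control comparison. In the fit with 1 library per knockdown, the lone library is assumed to vary like the others, and 26 of the 28 residual degrees of freedom come from set B, whose pairs lie closer than those of set A. The test was checked on simulated data built from these values: for shMed4 it recovered 52 of 80 genes changed by 0.5 on the log2 scale, 76 of 80 changed by 1 and 40 of 40 changed by 2, with 9 false calls, and 0 genes in a comparison without change. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.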

Results

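Levels of 24206 named genes were available as RPKM in 100 mRNA libraries of V6.5 mouse embryonic stem cells, 2 for each of 47 knockdowns and 3 control groups. The design text names the purpose: to find subunits of TFIID and Mediator that contribute more to global transcription and share most of their effects. It names TAF12 and MED4 as key subunits. TFIID is the general transcription factor that binds core promoters, and Mediator is the coactivator that bridges transcription factors and RNA polymerase II. Control set A holds 15 TFIID and 5 Mediator tail knockdowns, set B holds 23 Mediator and 2 SAGA knockdowns, and set C holds 2 Mediator knockdowns. The RPKM denominator had a median of 21.46 M reads in set A (17.25 to 25.81), 25.84 in set B (19.89 to 39.32) and 25.76 in set C (20.26 to 30.27). The spread between the 2 libraries of a group, as the mean chi-square of their read numbers (expectation 1 for sampling alone), had a median of 2.18 in set B, 16.94 in set A and 36.56 in set C. A library's nearest neighbour was its own partner for 52 of 52 libraries in set B, 1 of 42 in set A and 0 of 6 in set C.

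The first question was whether each target transcript fell. In set B all 25 targets were among the 2 lowest libraries of the set in both replicates, at a median of 26.6% of the control mean in replicate 1 (14.2 to 60.5) and 27.3% in replicate 2 (14.5 to 68.9). Kat2a fell by 2.33 ± 0.10 on the log2 scale (adjusted p = 2.15e-28), Med19 by a log2 change of -2.29, Ccnc by -2.23 and Med18, the weakest in this set, by -0.53 (5.13e-06). In set A the libraries labelled replicate 2 had 20 of 20 targets among the 2 lowest (median 34.1% of control, 15.9 to 59.0). The libraries labelled replicate 1 had 0 of 20 (median 102.4%, 56.9 to 172.7). In set C the libraries labelled shMed1 and shMed14 replicate 1 had their targets at 66.0% and 61.5% of control, and those labelled replicate 2 at 97.9% and 99.1%. The library labelled shMed1 replicate 2 had Med14 at 4.98 RPKM (controls 7.14 and 7.74), and the one labelled shMed14 replicate 2 had Med1 at 7.44 RPKM (11 and 11.9). In the fit of all libraries 43 of 47 targets were called lower. Taf4 (adjusted p = 0.085), Taf4b (0.090), Taf5 (0.137) and Taf6 (0.203) were not. A second fit, added after the levels were seen, leaves out the 22 libraries whose target was not among the 2 lowest of its set, one of which had Med16 at 56.9% of control; chosen by target level, it cannot test the targets. Because labels and target levels disagree in sets A and C, their samples are named below only by label.

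**Figure D1:**
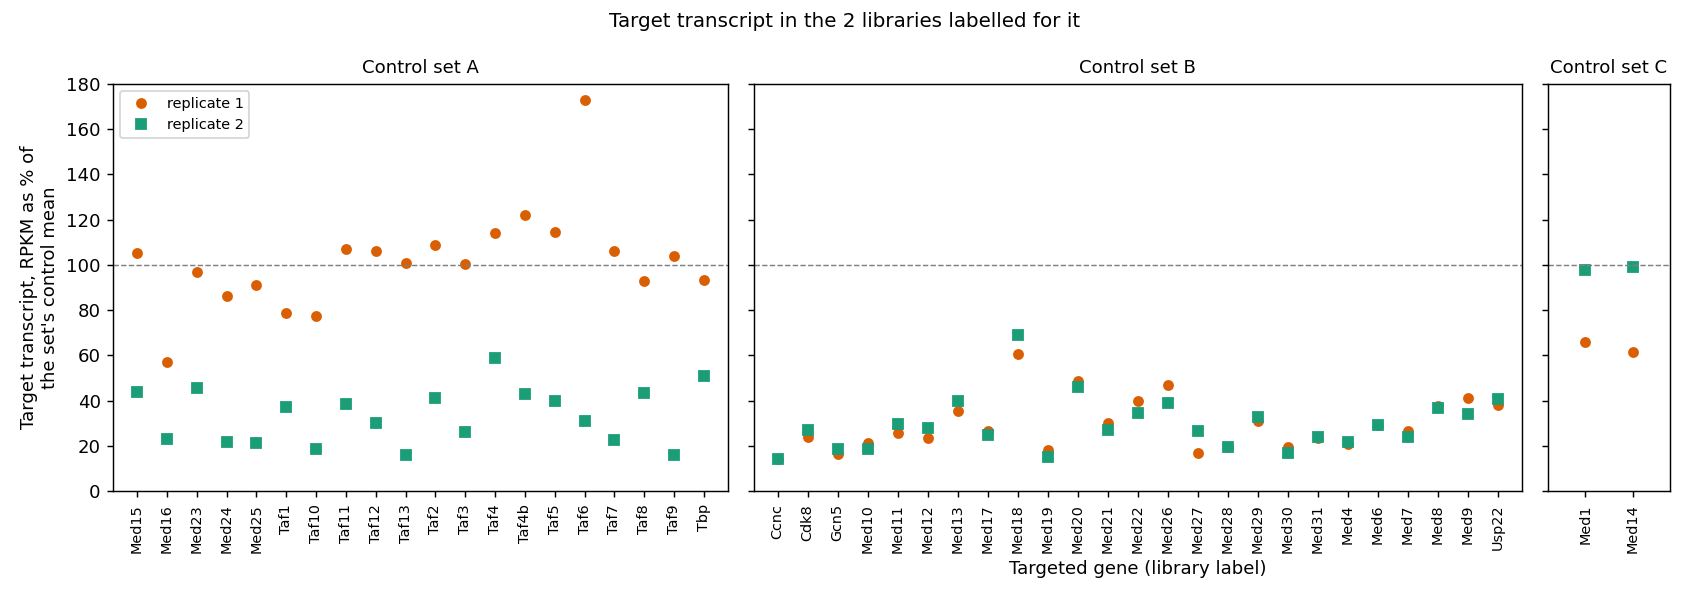
Each target's RPKM as a percentage of the mean of its control set (vertical axis, dashed line at the control mean) in the libraries labelled replicate 1 (circles) and replicate 2 (squares). In set B both replicates lie between 14.2% and 68.9%, whereas in set A replicate 1 lies between 56.9% and 172.7% and replicate 2 between 15.9% and 59.0%.

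After knockdown of Med4, a subunit of the Mediator middle module, 4196 of 12974 genes changed, 2182 up and 2014 down (limma). Med4 itself fell from 24.6 ± 0.408 to 5.26 ± 0.154 RPKM (SD, n = 2 in each group), a log2 change of -2.03 ± 0.09 (adjusted p = 2.81e-26). Acta1, the skeletal muscle actin, rose from 9.76 ± 0.757 to 133 ± 6.66 RPKM (log2 3.64 ± 0.54, adjusted p = 1.78e-06), and the smooth muscle actin Acta2 from 3.36 to 51.5 RPKM (3.60 ± 0.64, 3.18e-05). Tagln rose from 34.7 to 267 RPKM (2.91 ± 0.45), Csrp1 from 37.9 to 235 RPKM (2.60 ± 0.36), Cnn1 by 2.86, Actc1 by 2.98, Anxa1 by 2.58 and Wls, a carrier of Wnt ligands, by 2.50. The lowest were Nphs1 (-2.21 ± 0.34), Nr0b1 (-2.19 ± 0.36; 31.9 to 6.21 RPKM), Tcf15 (-2.16 ± 0.33; 109 to 23.6 RPKM), Cobl (-2.09), the growth factor Fgf4 (-1.99 ± 0.41; 30.7 to 6.97 RPKM), Nlrp4f (-1.99) and Mymx (-1.92). Reads of the 3 actin transcripts are partly alike, and how shared reads were assigned is not given in the sources used here. The count fell to 2252 without shMed4 replicate 1, 2458 without replicate 2, 2340 without control_B replicate 1 and 2408 without its replicate 2, was 436 at an absolute log2 fold change of at least 1 and 7918 with the libraries of set B alone.

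**Figure D2:**
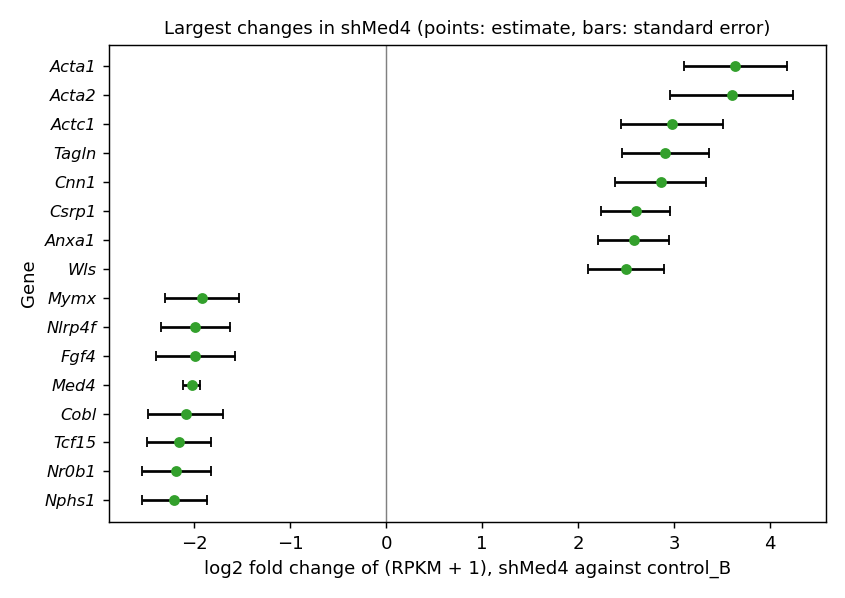
Log2 fold change of RPKM + 1 in the 2 shMed4 libraries against the 2 control_B libraries (horizontal axis) for the 8 highest and 8 lowest named genes; points are estimates and bars standard errors. The values run from 3.64 for Acta1 to -2.21 for Nphs1.

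Among the genes of pluripotency in the shMed4 libraries, 9 of 12 general and 9 of 14 naive genes fell and 0 rose, with the same counts adjusted over the list alone. Nanog went from 59.6 to 28.1 RPKM (log2 -1.06 ± 0.25), the Nodal coreceptor Tdgf1 from 276 to 105 (-1.39), Klf4 from 35.1 to 13.2 (-1.34), and Zfp42, a naive marker, from 73.8 to 28.8 (-1.33). Camera called both lists lower than other genes (adjusted p = 1.71e-04 and 9.25e-05). Neither call held with an estimated correlation, where the adjusted p = 0.576 for each. Of 10 primed genes, Cdh2 rose (0.92) and Dnmt3a fell from 34 to 9.62 RPKM (-1.72), and 8 did not pass; 1 up and 1 down were also called over the list alone, and camera did not call the list. In the trophectoderm list, 6 of 10 genes rose and 8 of 10 when adjusted over the list alone. The keratins Krt8 (45 to 227 RPKM, 2.31 ± 0.33), Krt18 (66.7 to 320, 2.24) and Krt7 (1.97) rose with Tead4 (0.93). The list was called higher (adjusted p = 9.25e-05; adjusted p = 0.576 with an estimated correlation).

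Other lineage lists moved in fewer members. Of 4 mesendoderm genes tested, Wnt3 (1.18 to 7.2 RPKM, 1.91 ± 0.41) and T (0.488 to 1.81, 0.91 ± 0.26) rose. In the primitive endoderm list Sparc rose (1.15) and Cubn fell (-1.76), with 13 of 15 not passing. Of 6 neuroectoderm genes Nes rose (1.31) and Sox1 (-1.24) and Tubb3 (-0.66) fell. Of 10 germline genes Stra8 alone fell (-1.68; 6.24 to 1.28 RPKM), and 0 of 6 two-cell-like genes passed. Of 10 Hox genes 4 rose, Hoxb9 by 1.10. Counts over the list alone were equal for these 6 lists, and camera called none of them. Of 8 tested markers of fibroblast feeders, 4 rose both over all genes and over the list alone: Acta2, Tagln, Col5a2 (1.17 ± 0.17) and Fbn1 (0.60). That list was called higher (adjusted p = 0.003; adjusted p = 0.576 with an estimated correlation). The abundant fibroblast collagens stayed low: Col1a1 was at 1.33 RPKM against 0.386 (adjusted p = 0.096) and Col1a2 at 0.401 against 0.299 (0.772).

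Of 21 targets of p53, 11 rose in the shMed4 libraries (13 over the list alone), among them the cyclin-dependent kinase inhibitor Cdkn1a (28.6 to 90.6 RPKM, 1.63 ± 0.31), Polk (0.76) and Eda2r (0.65); the list was called higher (adjusted p = 3.78e-04; adjusted p = 0.595 with an estimated correlation). In the ribosome biogenesis list 15 of 16 fell over all genes and over the list alone, such as Wdr12 (-0.65 ± 0.13) and Rrp1b (-0.56), with adjusted p = 2.27e-06 for the list (0.576 with an estimated correlation). Of 15 G1/S genes 10 fell (14 over the list alone), Ccne1 by a log2 change of -0.95 ± 0.18 (adjusted p = 9.80e-05 for the list; adjusted p = 0.576 with an estimated correlation). Of 14 G2/M genes 10 fell (12 over the list alone), Cdc20 by -0.62 and Ccnb1 by -0.57 (1.08e-04; adjusted p = 0.595 with an estimated correlation). Of 20 ribosomal protein genes, whose reads can come from pseudogenes, Rps6 (-0.50), Rpl5 (-0.31) and Rpl8 (-0.43) fell, 3 also over the list alone, and the list was called lower (0.003; adjusted p = 0.608 with an estimated correlation). Of 17 genes of the integrated stress response 10 fell and 1 rose in both counts, including the amino acid transporter Slc7a3 (40.5 to 11 RPKM, -1.79), Chac1 (-1.34), Mthfd2 (-1.10) and Atf4 (-0.62); adjusted p = 0.017, and adjusted p = 0.597 with an estimated correlation. Of 17 genes of hypoxia and glycolysis 5 fell in both counts, Pdk1 by -1.42 and Ldha by -0.74 (0.026; adjusted p = 0.608 with an estimated correlation). The estimated correlation comes from the differences between the 2 libraries of every group. In sets A and C these include pairs whose labels and target levels disagree, so it can hold differences between knockdowns. None of the 11 camera calls in the shMed4 libraries held with an estimated correlation in the fit of all libraries, and fry placed 17 of the 34 lists under an adjusted p of 0.05. In the fit of 78 libraries, which keeps these 4 libraries and pools a smaller spread, 7 lists held with an estimated correlation: general (adjusted p = 0.004) and naive pluripotency (0.009), trophectoderm (0.009), p53 targets (0.017), ribosome biogenesis (0.001), G2/M (0.008) and the feeder list (0.017).

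The remaining lists were not called by camera in the shMed4 libraries. Heat shock genes split, with 7 of 10 lower (Hspd1 -0.75, Hsph1 -0.53) and 2 higher (Bag3 0.78), and 7 and 2 over the list alone. Of 11 immediate early genes 6 rose (Ccn1 1.76, 45.4 to 156 RPKM; Junb 1.44) and 2 fell (Egr1 -0.90, Myc -0.83). Of 10 ERK targets 3 rose and 3 fell (3 and 5 over the list alone), Phlda1 by 1.31 and Spry4 by -1.14. Of 10 Wnt targets 4 rose, including Axin2 (0.64) and Sp5 (1.39), and Notum fell (-1.49). Of 11 TGF-beta and BMP targets 5 rose (Id3 1.24), with 5 up and 2 down over the list alone. Of 10 LIF-Stat3 targets 4 fell, such as Gbx2 (-1.75) and Socs3 (-0.59), and 2 rose. Of 18 imprinted genes 5 rose, including Peg3 (4.42 to 17.1 RPKM, 1.74), Igf2 (1.29) and Sgce (1.14), and 3 fell, including the growth inhibitor Cdkn1c (-1.23). Of 20 cholesterol synthesis genes 4 rose (3 over the list alone), and of 6 interferon response genes Cxcl10 rose (0.87; 0 over the list alone). In the lists of the transcription machinery, 0 of 15 TFIID subunits passed, 2 of 5 TFIID paralogs fell (Taf5l -0.46, Taf6l -0.42), 2 of 33 Mediator subunits fell (Med4, and Cdk8 by -0.25) and Med12l rose (0.70). Of 21 SAGA subunits 5 fell (Kat2b -0.83) and 2 rose (Atxn7 0.46), 5 of 17 general transcription factors fell (Gtf2h4 -0.41), and of 12 Pol II subunits Polr2a rose (0.60) and 3 fell, or 6 over the list alone (Polr2i -0.57). For the other lists in this paragraph the counts over the list alone were equal. Median and mean log2 changes had opposite signs for the germline (0.05 and -0.16), imprinted (-0.03 and 0.08) and SAGA (0.03 and -0.08) lists.

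The libraries labelled shTaf12 gave 6 called genes against control_A, 4 up and 2 down. TAF12 is a histone-fold subunit of TFIID that is shared with SAGA. Taf12 was at 17.1 and 4.86 RPKM in these libraries against 14.9 and 17.2 in the controls (log2 -0.73 ± 0.30, adjusted p = 0.419 over all genes and 0.020 over the 47 targets). In the same order Taf11 was at 5.46 and 18.4 RPKM against 18.3 and 18.5 (-0.79 ± 0.22, adjusted p = 0.173). The 4 genes that rose were the autophagy kinase gene Ulk2 (0.76 ± 0.15, adjusted p = 0.015), Katnbl1 (0.56 ± 0.10, 0.007), Nfatc3 (0.49 ± 0.09, 0.007) and Fmr1 (0.41 ± 0.08, 0.016). Slc52a3 fell (-0.72 ± 0.14, 0.015); it is under 3 RPKM in every one of these libraries and lies outside the naming rule. Among the lists, 0 members passed over all genes, while over the list alone 5 of 10 germline and 4 of 10 heat shock genes were lower and 2 of 6 interferon response genes higher, and 1 or 2 members passed in 6 other lists. Camera called 8 lists, 7 of them lower, such as ribosomal protein (adjusted p = 1.13e-10; adjusted p = 0.346 with an estimated correlation), germline (2.59e-06; adjusted p = 0.206 with an estimated correlation) and heat shock (8.95e-04; adjusted p = 0.262 with an estimated correlation), and interferon response higher (0.006; adjusted p = 0.206 with an estimated correlation). The other calls, all lower, were two-cell-like, G1/S and the integrated stress response (0.006 each) and ribosome biogenesis (0.004), with adjusted p = 0.605 or 0.608 with an estimated correlation. The count of called genes was 1293 without shTaf12 replicate 1, 2 without replicate 2, 3 without control_A replicate 1 and 0 without its replicate 2.

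With the replicate 2 library labelled shTaf12 alone, in the fit of 78 libraries added after target levels had been seen, 6259 genes passed, 3753 up and 2506 down. Of the 28 residual degrees of freedom of that fit 26 come from set B, whose pairs lie closer (mean chi-square per gene 2.18 for control_B) than the control_A pair (9.27), so its p-values for set A use a smaller spread than that pair shows and are likely to be too small. The median over the groups of set A (16.94) and the 0 genes that passed with all libraries of set A alone include pairs whose labels are in doubt, so they do not measure the noise of 1 library. The fit also sets replicate 2 libraries of set A against the mean of both control_A libraries. A difference between replicates 1 and 2 of the set can therefore enter every fold change. One unnamed transcript was at 5935.2 RPKM in control_A replicate 1 and 2731.0 in replicate 2. No transcript exceeded 1824.6 RPKM in the library labelled shTaf12 replicate 2. The counts and list results of this fit for set A, here and below, describe 1 library per knockdown, and the number of genes changed is not established. After upper-quartile scaling of the same fit 46.7% of the called genes were higher in place of 60%, so the balance of directions depends on the scaling. Taf12 fell by 1.54 on the log2 scale. After each list below the first adjusted p is camera's at the preset correlation and the second is the adjusted p with an estimated correlation. Of 15 primitive endoderm genes 14 rose, Sox17 by 1.07 and the adaptor gene Dab2 by 1.07 (6.56e-08; 0.038). In the trophectoderm list 7 of 10 rose, Gata3 by 1.83 and Krt18 by 1.21 (7.52e-04; 0.038), and among imprinted genes 10 of 18 rose and 2 fell, with Igf2 at 1.73 and Peg10 at 1.41 (0.012; 0.028). All 20 ribosomal protein genes fell, Rps9 by a log2 change of -0.70 (9.76e-14; 0.047), with 12 of 16 ribosome biogenesis genes (Dkc1 -0.71; 7.61e-08; 0.002), 13 of 15 G1/S genes (Ccne1 -0.95; 8.92e-07; 0.034) and 10 of 14 G2/M genes (Ube2c -0.72; 2.97e-05; 0.027). Of 12 general pluripotency genes 9 fell and 1 rose, Pou5f1 by -0.70 and Utf1 by -0.86 (2.93e-05; 0.019), 9 of 10 germline genes fell (Ddx4 -1.27; 1.21e-05; 0.027), and of 17 genes of the integrated stress response 11 fell and 2 rose (Nupr1 -2.12; 2.34e-06; 0.028). Counts over the list alone were equal, except for ribosome biogenesis with 14. In this fit camera called 20 lists and 15 of them held with an estimated correlation.

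The next question was how far the effects of TFIID and Mediator subunits overlap. All 6 genes called in the libraries labelled shTaf12 were also called in one direction in the shMed4 libraries: 4 up where 0.673 would be expected by chance (Fisher's exact test, p = 7.98e-04) and 2 down where 0.31 would be (p = 0.024). Nfatc3 rose by 0.58 and Ulk2 by 0.83 in the shMed4 libraries. Of the 4 shared rises, Nfatc3, Katnbl1 and Fmr1 also rose in 12 or more of the 15 TFIID labels, and the shared count was 0 with the libraries of each control set alone and 0 against the other knockdowns of the set. A rise common to most knockdowns of a set cancels against the others. The shared count was 796 without shTaf12 replicate 1, 1 without replicate 2, 3 without control_A replicate 1 and 0 without its replicate 2. With the replicate 2 library alone, 4432 genes were shared, 2438 up (expected 1070, odds ratio 11.8) and 1994 down (expected 766, odds ratio 16.8). The change differed between the libraries labelled shTaf12 and the shMed4 libraries in 411 genes, with 108 relatively higher under the shTaf12 label and 303 relatively lower; with 1 library per knockdown the balance turned, to 1824 higher and 1389 lower. Those relatively lower were led by Acta1 (difference -3.47 ± 0.77, adjusted p = 0.009), Acta2 (-3.23), Actc1 (-2.72), Tagln (-2.56), Csrp1 (-2.46) and Krt19 (-2.43 ± 0.43, 0.001), and those relatively higher by Cubn (2.35 ± 0.33, 1.24e-05; 0.59 in shTaf12 and -1.76 in shMed4), Med4 (1.96), Nphs1 (1.81), Nr0b1 (1.73) and Slc7a3 (1.65). The 411 became 3213 with 1 library per knockdown, 23 without shTaf12 replicate 1, 1903 without shTaf12 replicate 2, 51 without shMed4 replicate 1, 76 without shMed4 replicate 2, 92 without control_A replicate 1, 110 without control_A replicate 2, 61 without control_B replicate 1 and 71 without control_B replicate 2.

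Knockdowns differed widely in how many genes changed. In set B the count ran from 5 for shMed18 to 4990 for shMed10 (median 75 over 23 Mediator knockdowns). The medians were 29 for 7 head, 871 for 8 middle, 38 for 4 kinase and 1974.5 for 4 tail subunits. The tail group of set B was Med27, Med28, Med29 and Med30, so the order of the modules depends on that assignment. After shMed10 and shMed4 (4196) came shMed12 (3600), shMed28 (3498), shMed30 (3496), shMed19 (1940), shMed17 (1776) and shMed7 (1452). These counts use a spread pooled over all sets. With the libraries of set B alone, the 23 Mediator counts ran from 1101 for shMed18 to 8378 for shMed10. A small count in the pooled fit thus does not show that a knockdown changed few genes. In the shMed10 libraries Acta2 rose by 4.32 ± 0.64, Actc1 by 3.79 and the myelin gene Pmp22 by 3.53, and Mymx (-2.95), Nr0b1 (-2.73) and Cobl (-2.39) fell. The shMed12 libraries had Acta2 up by 4.68 ± 0.64 (3.36 to 110 RPKM), Actc1 by 3.87 and Pmp22 by 2.91, with Tcf15 (-2.51), Nr0b1 (-2.37) and Gbx2 (-2.36) down. In shMed28, Wls (2.34) and Unc5b (2.29) rose, and Tcf15 (-2.52), the metallothionein Mt1 (274 to 51.1 RPKM, -2.40 ± 0.21) and Gbx2 (-2.21) fell. In set A the 15 sets of libraries labelled for TFIID subunits had a median of 12 called genes (0 for Tbp to 882 for Taf1), and 5 labelled for tail subunits a median of 69 (21 to 1060). In set C the libraries labelled shMed1 and shMed14 each gave 0 (limma), with 1372 and 1185 genes at an unadjusted p under 0.05 (968 for shTbp), and 5 and 5396 with 1 library each. As each of these 2 groups holds one library with the other target low, their counts of 0 do not show that a knockdown had no effect. The 0 for the shTbp label averages a replicate 1 library with Tbp at 93.3% of control and a replicate 2 library with 50.9%. The former was nearest to control_A replicate 1 (r = 0.9964). That 0 does not show that losing Tbp had no effect either. Over all 30 Mediator knockdowns the median was 68.5. With 1 library per knockdown in sets A and C the medians were 3509 for TFIID (831 to 6259) and 2639 for Mediator. The TFIID median was 3 without control_A replicate 1 and 0 without its replicate 2, and the Mediator median was 45.5 without control_A replicate 2 and 24.5 without either control_B library.

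**Figure D3:**
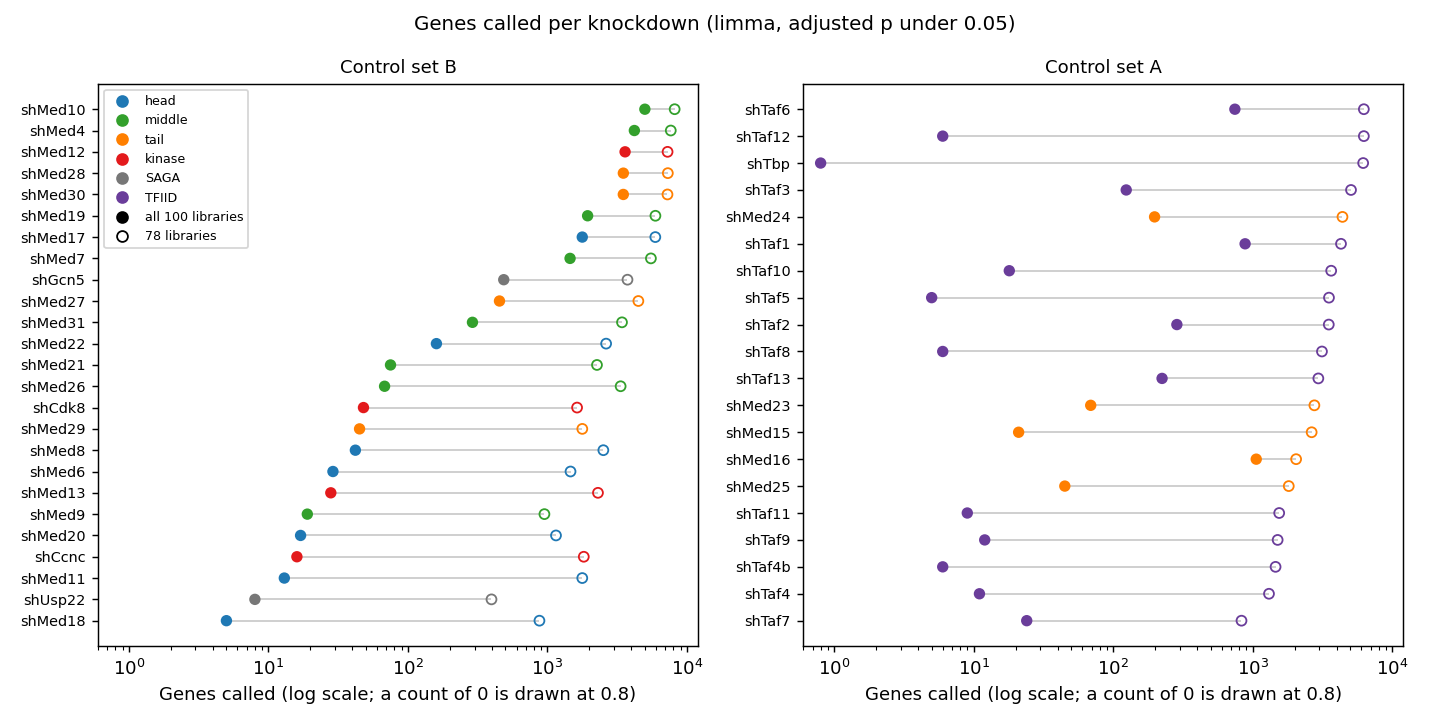
Number of genes called per knockdown (horizontal log axis, limma, adjusted p under 0.05) in the fit of all 100 libraries (filled) and in the fit of 78 libraries (open), coloured by module or complex. In set B the filled counts run from 5 to 4990, and in set A from 0 (drawn at the left edge) to 1060.

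A few genes were called in most knockdowns. In set B the transcription factor gene Nfatc3 rose in 23 of 23 Mediator knockdowns (mean log2 0.60, range 0.47 to 0.70), Srpr, a subunit of the receptor for the signal recognition particle, in 22 (0.67), Katnbl1 in 22 (0.49), Pgam5 in 21 (0.50), Erbin in 20 (0.75), Wdr77 in 19 (0.36), Rp2 in 17 (0.58) and Sh3bgrl2 in 15 (0.55). The genes called lower most often were Stra8 (14, -1.07), Tnfsf12 (14, -0.96), Cdkn1c (14, -0.91), Gsx1 (13, -1.03), Tnfsfm13 (12, -0.93), which overlaps Tnfsf12 so that both can count shared reads, Fbp2 (12, -0.83), Manba (11, -0.60) and Myc (11 lower and 1 higher, -0.56). Among 15 TFIID labels of set A, Nfatc3 rose in 14 (0.45), Srpr in 12 (0.53), Katnbl1 in 12 (0.51), Fmr1 in 12 (0.39), Pgam5 in 11 (0.45), Wdr77 in 7, Snrk in 6 and Ulk2 in 6. Aard fell in 6 (-0.77) and Ntn1, Ddx4, Tgm1, As3mt, Elovl6, Hspd1 and Rpl27a in 5 each. At the fixed minimum of 12 of 23, Mediator had 23 recurrent genes (16 up, 7 down), and at 8 of 15, TFIID had 8 (6 up, 2 down). With the libraries of each set alone these were 2203 and 0, and against the other knockdowns of the set 0 and 0. A change common to most knockdowns of a set cancels against the others, so the last 2 counts follow largely from that reference. Simulated unchanged groups against shared controls gave 0 in each of 20 simulations. No gene was changed in them, so the adjusted threshold passes almost nothing. They cannot show whether shared controls make genes recur in the real data. The Mediator count was 5 without either control_B library and the TFIID count 3 without control_A replicate 1 and 0 without its replicate 2, and with 1 library per knockdown in set A they were 1939 and 1654. In that fit Tagln (mean 1.42) and Csrp1 (1.20) rose and Dnmt3a (-0.98) and Sall1 (-0.55) fell in 23 of 23 Mediator knockdowns. In the fit of all libraries these were called in 9, 9, 10 and 9 of 23. Over the 15 TFIID labels Zadh2 had a mean log2 change of 0.82 with replicate 2 libraries alone. It was 0.43 with all libraries, where 0 of 15 labels had it called. The larger Zadh2 rise thus rests on the replicate 2 libraries and is not shown to be an effect of TFIID. Lncenc1 was at -1.28 with replicate 2 libraries alone and -1.25 with all libraries, where it was called lower in 4 of 15.

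**Figure D4:**
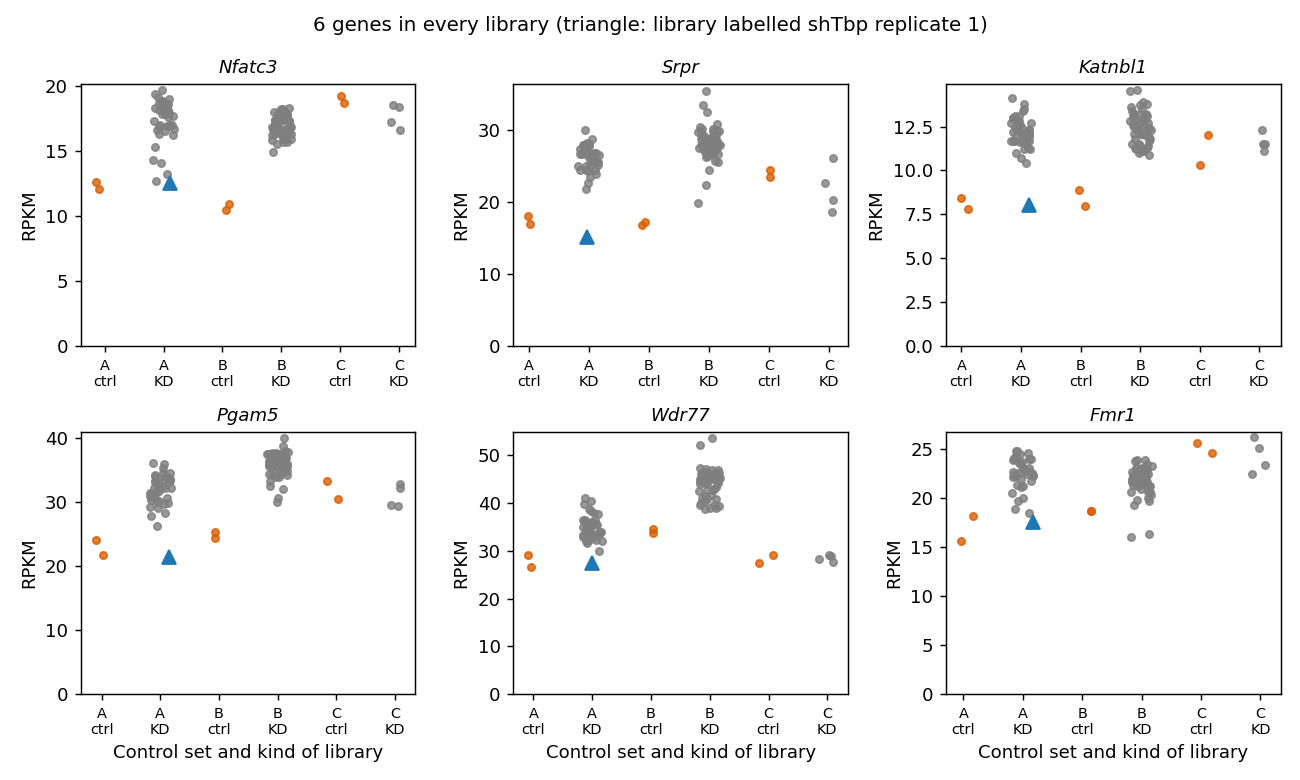
RPKM (vertical axes, from 0) of 6 recurrent genes in each library, by control set and kind (ctrl, control; KD, knockdown); points are single libraries and the triangle is the library labelled shTbp replicate 1. For Nfatc3 the 2 controls of set B lie at 10.5 and 10.9 RPKM and its 50 knockdown libraries between 14.9 and 18.3.

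Within set A, the libraries labelled for TFIID subunits differed from those labelled for the Mediator tail in 2503 genes, 1601 higher and 902 lower with TFIID. The label is the unit here (15 against 5), and the controls cancel. Most replicate 1 libraries hold the target of another label low, such as Taf13 at 8.83% of control in the one labelled shMed15, so the 20 means can mix knockdowns across both groups and are not 20 independent ones. Higher with TFIID were the Wnt effector Lef1 (8.9 ± 2.14 against 4.33 ± 1.38 RPKM, SD over knockdowns; log2 0.88 ± 0.14, adjusted p = 7.40e-04), Tcf15 (0.86), the immediate early gene Egr1 (18.5 against 10.4 RPKM, 0.82 ± 0.12), Calca (0.76), Mmp11 (0.69), Nqo1 (0.67) and the histone genes H2bc4 (0.83) and H4c9 (0.78), which have near copies. Lower were AU018091 (13.2 against 27.1 RPKM, adjusted p = 7.89e-05), Lncenc1 (-0.88), the imprinted RNA H19 (7.75 against 15.6 RPKM, -0.84 ± 0.14), Slc5a5 (-0.80), the galectin gene Lgals1 (70.7 against 122 RPKM, -0.79), Klhl13 (-0.74) and Ddx4 (-0.72). Among the lists, 6 of 15 primitive endoderm genes were higher (9 over the list alone; Dab2 0.60, Gata6 0.48), as were 5 of 10 primed genes (6; Otx2 0.40, Dnmt3a 0.47), 7 of 17 general transcription factors (9; Gtf2a1 0.40) and 9 of 33 Mediator subunits (9; Med22 0.27). Lower were 6 of 10 trophectoderm genes (7 over the list alone; Tfap2c -0.66, Krt7 -0.66), 6 of 10 germline genes (6, with 1 higher) and 6 of 6 two-cell-like genes (6), whose members of the Zscan4 family are near-identical. With replicate 2 libraries alone the adjusted p was above 0.05 for H2bc4 (0.069), H4c9 (0.092), Nqo1 (0.063), Otx2 (0.104), Dnmt3a (0.161), Gata6 (0.264), Krt7 (0.054), Med22 (0.112), Zscan4a (0.108), Zscan4b (0.134), Zscan4c (0.095) and Zscan4f (0.170). The count was 1554 without shMed23, 67 with replicate 1 libraries alone, 863 with replicate 2 alone (770 of them among the 2503) and 105 at an absolute difference of at least 0.5.

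Within set B, the kinase module (Ccnc, Cdk8, Med12 and Med13) was compared with 15 head and middle subunits, and 0 genes passed (limma; 389 at an unadjusted p under 0.05). The gene with the lowest adjusted p was Cox6b2, at 20.5 ± 2.99 RPKM in kinase and 29.9 ± 4.01 in head and middle knockdowns (log2 -0.52 ± 0.10, adjusted p = 0.518). Polr2a was at 74 against 96.1 RPKM (-0.37 ± 0.09) and was the 1 member of its list to pass over the list alone. Acta2 was at 36.8 ± 49.1 against 17.4 ± 22.5 RPKM (0.92 ± 0.70), Krt8 at 120 against 98.7 RPKM (0.23 ± 0.39), Tagln at 116 against 113 (0.04 ± 0.50; outside the naming rule) and Nanog at 50.3 against 52.7 (-0.02 ± 0.27; also outside it). A simulation at these group sizes recovered 78 of 80 genes changed by 1 and 68 of 80 changed by 0.5. It shifted genes of higher level by the same amount in all 4 kinase knockdowns, with independent noise. The real ones were not alike, as shMed12 had 3600 called genes and the others 16 to 48. The recovery in the simulation thus does not show how well a real difference would be found.

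The lists were also tested on the mean over a complex. Over 23 Mediator knockdowns of set B, 4 of 10 trophectoderm genes rose (7 over the list alone) and camera called that list higher (adjusted p = 6.62e-05). Lower were ribosome biogenesis (4.17e-04; 0 of 16 members passed), naive (0.010; 3 of 14 fell, 5 over the list alone) and general pluripotency (0.027; 0 of 12) and the integrated stress response (0.013; 0 of 17), and the feeder list was higher (0.044; 2 of 8, 3 over the list alone). For each of these 6 lists the adjusted p = 0.618 with an estimated correlation, while in the fit of 78 libraries 5 of them held with one: trophectoderm (0.005), ribosome biogenesis (0.004), general pluripotency (0.010), the integrated stress response (0.040) and the feeder list (0.033). Over 15 TFIID labels, germline genes were lower (3.42e-08; 3 of 10 fell, 6 over the list alone; adjusted p = 0.252 with an estimated correlation), as were ribosomal proteins (1.70e-12; 0 of 20, 18 over the list alone; adjusted p = 0.300 with an estimated correlation) and heat shock genes (6.22e-04; 1 of 10, 4 over the list alone; adjusted p = 0.300 with an estimated correlation). Primitive endoderm was higher (0.005; 0 of 15, 1 over the list alone) and the integrated stress response lower (0.022; 0 of 17), each with adjusted p = 0.744 with an estimated correlation. In the fit of 78 libraries germline and heat shock held with one (0.013 each). The calls over the 4 contrasts numbered 30 with the preset correlation, 0 with an estimated one and 18 with fry, and 29 with an estimated one in the fit of 78 libraries.

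The 3 control groups, which all carry a control plasmid, were compared to measure differences between the sets. Control_B differed from control_A in 552 genes (191 higher, 361 lower). Clu was at 34.7 RPKM in control_B and 196 in control_A (log2 -2.46 ± 0.30), and the basement membrane collagens Col4a1 (63 and 342, -2.42) and Col4a2 (-2.35) and the tissue factor gene F3 (-2.32) were also lower, while Zscan4f (3.76 and 0.766, 1.43 ± 0.34) and Aard (1.36) were higher. Control_C differed from control_B in 5492 genes (2517 higher, 2975 lower). Higher in control_C were Ndufa4l2 (15.4 and 0.265 RPKM, 3.70 ± 0.22), Egln3 (44.5 and 3.25, 3.42), Aldoc (2.87) and Bnip3 (80.8 and 10.8, 2.79 ± 0.16), and Id3 (-2.30) and Gbx2 (-2.25) were lower. Control_C differed from control_A in 6177 genes (3073 higher, 3104 lower), among them Krt18 (-2.96) and Krt8 (-2.76). With the fit of 78 libraries the first of these counts was 4573. Each knockdown was compared with the control of its own set, and Med1 and Med14 also with control_B as another setting.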

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

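The tests of a mislabelled sample, of a hairpin that did not work, of read numbers on the targets, of loss of Mediator alone, of chance values in the control_B libraries and of library scaling were chosen only after the result was seen, as was the comparison with other splits of the knockdowns. Of 5 groups of knockdowns examined for a count of called genes far from the rest, 3 held one, where chance gives about 1 in 20 for normally distributed values; these counts are skewed, so the rate here was not measured. Among 7 head knockdowns of set B, shMed17 had 1776 genes (the next had 160 and the lowest 5). Among 4 kinase knockdowns, shMed12 had 3600 (48 and 16). With the libraries of set B alone shMed17 had 6261 (the next, shMed22, had 2945) and shMed12 had 7523 (the next, shMed13, had 2653). Among 5 tail labels of set A, shMed16 had 1060 (198 and 21). Its 2 libraries were the least alike pair of set A (r = 0.9603). The one labelled replicate 1, with Med16 at 56.9% of control, was nearest to shMed10 replicate 2 of set B (r = 0.9831). The 1060 genes can thus not be assigned to the loss of Med16. The change in the libraries labelled shTaf12, where replicate 1 had Taf12 at 106% of control, differed from that in the shMed4 libraries in 411 genes by the test of the difference itself. The 2503 genes between the TFIID and tail labels were reached by 1 of 100 splits of the 20 labels, the real one, and the highest other split had 615, but label means that share a knockdown cannot be exchanged freely, so this split test alone does not exclude chance. With replicate 2 libraries alone, each with its own target low, 2 of 100 splits, the real one included, reached the real count of 863, a share under 0.05. The highest other had 2294, which points to a structure among these libraries other than the 2 complexes. Few splits thus give as many genes, but a test chosen after the result was seen does not exclude chance. Between the kinase and the head or middle knockdowns the real count was 0, which all 100 of 100 splits must reach, so the comparison says nothing about chance; the highest other had 971, which also points to a structure among the samples.

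In control set A, 0 of 20 targets were among the 2 lowest libraries in the one labelled replicate 1, and 1 of them, Med16 at 56.9%, was under 75% of control. Too few reads on the targets are argued against, since the target with the fewest had 423 in that library. A hairpin that failed in replicate 1 is argued against because 18 of the 20 targets were under 75% of control in a replicate 1 library labelled for another target (8.83 to 55.1%). The low libraries followed the order of the labels: each Taf target up to Taf12 was low under the label of the next Taf subunit. Examples are Taf1 in shTaf2 (40.4%), Taf11 in shTaf12 (29.6%) and Taf12 in shTaf13 (24.3%), while Taf13 was low in shMed15 and Tbp in shTaf1 (45.4%). For 15 targets the replicate 2 library nearest to that low library over all other genes was the target's own, as a mislabelled sample would give. For Med16, Taf2 and Taf7 it was another. Med24 and Med25 were at 81.3% and 80.7% in their lowest other library. A candidate explanation is therefore that labels of the replicate 1 libraries are displaced, and since no biological explanation was tested and the labels were kept as given, the counts for TFIID in the fit of all libraries may mix knockdowns of different subunits.

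The 16 genes that rose in at least 12 of 23 Mediator knockdowns had a median rise of 0.47 (0.41 to 0.58 between knockdowns), but single genes varied more, such as Ube4b (-0.10 to 0.63) and Gadd45b (0.24 to 1.66). Loss of Mediator alone is argued against by the replicate 2 libraries of the TFIID labels, which share no control with them, at a median of 0.36, and chance values of the control_B libraries by both TFIID replicates, at 0.33. That holds for the 10 genes at 0.25 or more in these TFIID libraries, Nfatc3, Srpr and Katnbl1 among them, while for the other 6, such as Nedd4l (-0.08) and Ube4b (0.04), both stay open. An effect of the control plasmid may be the source but was not decided: the 2 SAGA knockdowns gave 0.49 but share control_B, and in set C, whose controls hold Nfatc3 at 19 RPKM and differ from control_B in 5492 genes, the change was 0.00 for shMed1 and -0.01 for shMed14. A response shared by the loss of any of the 3 coactivators stays open and was not tested.

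In the shMed4 libraries 4 of 8 tested feeder fibroblast markers rose, and camera called the list higher at the preset correlation (adjusted p = 0.003) but not with an estimated one (0.576). Fibroblast RNA is argued against because the collagens Col1a1, Col1a2 and Col3a1, among the most abundant fibroblast transcripts, rose by 1.13 RPKM in sum while Tagln rose by 232 RPKM, and the protocol removed feeders before transfection. The scaling of the libraries, which would move every gene alike, is argued against because the median of all tested genes was -0.02 where that of the list was 0.68. ES cells of the controls also express Tagln (34.7 RPKM) and Acta2 (3.36 RPKM). A higher level of these contractile genes within the knockdown cells may be a biological effect of losing Med4, a hypothesis formed on the same data and not tested.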

How the results depend on the processing

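The fit with 1 library per knockdown in sets A and C, the gene level from the mean of transcripts, limma-voom and the upper-quartile control comparison were chosen only after the data were seen. Counts below are in the order genes in shTaf12, genes in shMed4, TFIID median, TFIID recurrent genes, Mediator median, Mediator recurrent genes, genes shared by shTaf12 and shMed4, and genes whose change differs between them; those not listed stayed within 1.5 times. In the fit of all libraries they were 6, 4196, 12, 8, 68.5, 23, 6 and 411. Without the filter on low values shTaf12 had 63, the TFIID median was 81 with 36 recurrent, the Mediator median 128.5 with 47, and 16 were shared; the cause was not tested. With the replicate block these were 16, 31, 18, 108, 37 and 14. At an absolute log2 fold change of at least 1 the 8 counts were 0, 436, 1, 0, 6.5, 1, 0 and 162. With the libraries of the same set alone the first 7 were 0, 7918, 0, 0, 2353, 2203 and 0, where a set with close or distant replicates keeps its own spread, and with sets A and B alone the difference was 760. With the 4 libraries of a comparison alone shTaf12 had 0, shMed4 7170 and 0 were shared, and with 8 libraries the difference was 9. Against the other knockdowns of the set, shTaf12 had 0, TFIID a median of 0 with 0 recurrent, Mediator 394.5 with 0, and 0 were shared. With that reference a change common to most knockdowns of a set cancels. With control_B for Med1 and Med14 the Mediator median was 117.5. Leaving out in turn each library of the comparison and its controls gave 0 to 1293 for shTaf12, 2252 to 2458 for shMed4, 0 to 796 shared and 23 to 1903 different. Leaving out each control library alone (no knockdown library was left out) gave 0 to 3 for the TFIID median and its recurrent genes, 24.5 to 63.5 for the Mediator median, 5 for its recurrent genes and 40 to 43 targets called lower. With 1 library per knockdown, the 8 counts were 6259, 7653, 3509, 1654, 2639, 1939, 4432 and 3213; no set B library is left out in it, so for shMed4 and the recurrent Mediator genes the rise comes from the smaller pooled spread. The TFIID and tail labels differed in 2503 genes, in 105 at an absolute difference of at least 0.5, 67 with replicate 1 alone, 863 with replicate 2 alone and 1554 to 2922 leaving out each knockdown in turn. Hoxa5 turned from 0.24 to -0.01 with replicate 1 alone. The 30 list calls became 0 with an estimated correlation, 18 with fry and 61 with 1 library per knockdown (29 of the lists with both that fit and an estimated correlation), and the control_B and control_A difference of 552 genes became 4573. The kinase comparison stayed at 0 in each setting run. For single genes, list members and counts not listed, 5961 values kept their side of the threshold and direction, 152 newly passed, 426 no longer passed and 1 turned, and 833, 142, 1 and 0 did so in the settings added later. Of the named genes called, 4 of 88 kept the call in every alternative between the TFIID and tail labels, 0 of 4 for shTaf12 and 88 of 115 for shMed4. Replicate numbers were not taken as pairs, since not every pair of groups correlated over 0.1: differences between replicates correlated between groups at -0.02 to 0.21 in set B (135 of 325 pairs of groups over 0.1), -0.57 to 0.69 in set A (125 of 210) and -0.70 to 0.18 in set C, so a shared replicate effect is not excluded in sets A and B. Precision is limited by 2 libraries per group, and where both libraries of a group differ in target level, by their labels. Depth limits the lowest levels: 1 read on a kilobase of transcript is at most 0.058 RPKM, which limits what can be read from genes near that level.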

Other observations

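The tests below were chosen after the values were seen for the depth of knockdown and for the SAGA genes; the test of module similarity was fixed earlier. The genes changed in the 2 SAGA knockdowns, of which only the targets and recurrent genes appear above, differed in number: shGcn5 gave 486 called genes and shUsp22 gave 8, of which 7 were also called in one direction in shGcn5. All 7 are among the 16 genes that rose in most Mediator knockdowns against the same control_B libraries. With the libraries of set B alone shGcn5 had 4223 called genes and shUsp22 had 536. The count of 8 thus depends on the spread pooled over all sets and does not show that losing Usp22 had no effect. In the shGcn5 libraries Kat2a, the acetyltransferase targeted by the hairpin, fell from 32.4 ± 0.771 to 5.65 ± 0.495 RPKM (SD, n = 2; log2 -2.33 ± 0.10). The hormone precursor gene Trh rose from 11.6 to 42.8 RPKM (1.80 ± 0.48, adjusted p = 0.018), Gpx2 from 3.75 to 11.6 RPKM (1.40 ± 0.25), Dppa3 from 3.18 to 9.56 RPKM (1.34 ± 0.33) and the lipid desaturase Scd2 from 15.7 to 33.7 RPKM (1.05 ± 0.18). Klf4 fell from 35.1 to 11.8 RPKM (-1.50 ± 0.21), Nr5a2 by a log2 change of -1.28, Msc by -1.41 and Pdgfa by -1.27 (15.5 to 5.86 RPKM).

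In the shGcn5 libraries 6 of 6 genes of the two-cell-like list fell, also over the list alone (median -1.08), with Zscan4f at 0.801 against 3.76 RPKM (-1.41 ± 0.34) and Zscan4c at 0.825 against 3.21 RPKM; members of this family share near-identical reads. In the germline list 6 of 10 fell (10 over the list alone; median -0.80), and in the naive list 4 of 14 fell and 1 rose (9 and 1 over the list alone). Of 20 cholesterol synthesis genes 4 rose (12 over the list alone; median 0.34), and of 10 primed genes Otx2 rose (21 against 9.81 RPKM, 1.03 ± 0.24; 4 up and 1 down over the list alone). Pdgfa and Otx2 were at 0.62 and -0.49 in shMed4. A difference between shGcn5 and shMed4 was not tested. In the shUsp22 libraries the median of the two-cell-like list was 0.57, and 0 of 6 genes passed. The control sets also differ in these genes, with Zscan4f at 0.766 RPKM in control_A and 3.76 in control_B.

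For each of 6 recurrent genes the library labelled shTbp replicate 1 was the lowest of the 40 knockdown libraries of set A, with Nfatc3 at 12.5 RPKM (controls 12.6 and 12.1), Srpr at 15.2 (18 and 16.9) and Fmr1 at 17.5 (18.2 and 15.6). Over all genes its nearest library was control_A replicate 1 (r = 0.9964, against 0.9732 with the other library labelled shTbp), and Tbp was at 93.3% of control in it.

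In set B, knockdowns with a lower remaining target had more called genes. Over 25 knockdowns the target's percent of control correlated with the logarithm of the count at Pearson's r = -0.66 (permutation p = 2.80e-04, adjusted 5.60e-04). Spearman's rho with the count was -0.64 (permutation p = 8.80e-04, adjusted 8.80e-04, 2 relations computed). Without shMed18 and shMed20, the 2 farthest from the median, r was -0.59 and rho -0.58. All of these knockdowns share 1 control group and 1 set. The depth of the knockdown may thus set part of the ranking of subunits.

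A hypothesis that subunits of one module give like profiles was not decided. The mean correlation within modules over the 23 Mediator knockdowns of set B, across genes and after removal of the common change, was -0.00, against -0.03 for permuted modules (permutation p = 0.226). Among head subunits it was 0.13 (permutation p = 0.054, adjusted 0.214 over 4 modules). The nearest profile was in another module for 18 of 23 knockdowns and in the same one for 5. Examples across modules are shMed4 with shMed30 (r = 0.75), shMed12 with shMed4 (0.70) and shMed28 with shMed4 (0.66), and within one shMed10 with shMed4 (0.71) and shMed18 with shMed20 (0.65). Subtracting the mean of the 23 knockdowns makes weak knockdowns like each other and opposite to strong ones. The shMed4 profile was at r = -0.705 with shMed18 and -0.722 with shMed20, which had 5 and 17 called genes. Nearest profiles and module means can thus reflect the strength of a knockdown, so they do not decide whether modules are alike. Genes are not independent replicates in these correlations.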
